A study of Homo sapiens with 3 samples.

How the data were processed

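RNA-seq libraries of hepatocyte-differentiated H9 cells from day 25 were used, 3 in all, with 1 library for each of the labels WT, AAVS1-PD-L1/CTLA4Ig and ALB-PD-L1/CTLA4Ig. Groups were taken from the genotype labels. Per the labels' protocols, messenger RNA was selected with poly-T beads, fragmented, copied with random primers and amplified by PCR, and paired ends were read on an MGI instrument. The labels name different RNA extraction methods, Trizol in the design text and a miRNeasy kit in the sample protocol, and which was used is not settled here. Poly-T selection leaves out most RNA without a poly-A tail, and PCR without molecular identifiers means that fragments are not independent molecules.

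The deposited values are FPKM, fragments scaled by gene length and by the total of the library, computed by the authors for 35207 genes with Ensembl identifiers. The aligner, the counter and whether the counting used strand are not given in the sources used here. The submitters' processing notes list hg19 and GRCh37. The values themselves fit gene lengths of GENCODE 29, which is built on GRCh38: each FPKM above 0 times the joined exon length of its gene was a whole multiple of the value of 1 fragment, within 0.001 of a whole number, for 100% of values in each library. The build used for alignment is thus not settled, and the positions in the text are those of the GRCh38 annotation. Of the identifiers, 34946 matched the table of gene names.

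Fragments recovered this way summed to 24953520 (WT), 24712091 (AAVS1) and 24029728 (ALB), and they served for intervals and not for a count test. A value of 3 fragments on a gene of 1 kb, taken as the floor, was 0.120, 0.121 and 0.125 FPKM. Exact Poisson intervals were given for FPKM values, and intervals of ratios came from Clopper-Pearson limits on the share of fragments in the first library, all at 95% and for counting error only. The FPKM unit divides by the whole joined exon length, so a gene with long rare exons has a low value.

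The size of a difference was that of log2(FPKM + 1), which understates the change of low genes, over 13501 genes with a mean over the 3 libraries of at least 1 FPKM. Genes at or past 1 on that scale, 2-fold, were counted. Counts from 100 simulations in which libraries differed by counting error alone stand beside them. With 1 library per label no test was run. Ratios printed for genes are ratios of FPKM, with no pseudocount.

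The 45 gene lists were fixed before the data were examined, as were the comparisons, the size rule and most alternatives. Each list median was set as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The top bin held every gene with a mean above 52.5 FPKM, so the far more abundant mitochondrially encoded genes were matched less closely. Random lists also do not carry any tendency of list members to move together. A list below the percentile 2.5 or above 97.5 is said to stand apart, and a list with fewer than 4 members at a mean of at least 1 FPKM got no percentile. Some lists share members, such as DES, FOXA2, CXCL8 and AFP.

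Named genes followed a rule fixed beforehand. It took CD274, CTLA4, ALB, PPP1R12C and the IgG constant region genes, and per comparison the 8 protein-coding genes with the highest and the 8 with the lowest log2 difference at a mean of at least 5 FPKM. It also took the members highest in mean FPKM and highest and lowest by ratio in each list described, and all members of lists of up to 6 members at a mean of at least 1 FPKM.

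The steps were tested on simulated data for ALB against WT with 13473 genes, of which 200 were changed. Fragments were recovered exactly for 100% of values. The 2-fold rule found 0% of 68 genes changed 1.25-fold, 100% of 63 changed 3-fold and 100% of 69 changed 4-fold. A list of 20 genes shifted by 0.1 reached the percentile 100.0 and an unshifted one 18.2. Intervals held the true ratio for 95.4% of 16329 unchanged genes. These were simulated with counting error alone, so the share does not carry over to real libraries that vary beyond counting error.

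Alternatives were a pseudocount of 0.1, rescaling of each library to a common sum as TPM does, median-ratio size factors, rescaling without the 50 most abundant genes, no filter, a mean of at least 5 FPKM, and the mean of list members in place of the median. Counts with protein-coding genes alone and with at least 50 fragments were added after seeing the data. Summing rows that share a symbol was planned as well. Exon overlap between genes was measured on the GENCODE 29 annotation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.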

Results

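RNA was sequenced from H9 cells, a human embryonic stem cell line, that had been differentiated toward hepatocytes and collected on day 25. The 3 libraries carry the labels WT, AAVS1-PD-L1/CTLA4Ig and ALB-PD-L1/CTLA4Ig, with 1 library for each. PD-L1, encoded by CD274, is a ligand that restrains T cells through the receptor PD-1, and CTLA4Ig joins the outer part of CTLA4, which binds CD80 and CD86, to an immunoglobulin constant part. AAVS1 is a site within PPP1R12C that is often used for insertion because many cell types tolerate it, and ALB encodes albumin, the main protein secreted by hepatocytes. The series title concerns protection of transplanted cells from the host's immune response by making both proteins in a chosen cell type. The libraries held 24953520 (WT), 24712091 (AAVS1) and 24029728 (ALB) fragments assigned to genes, and 30435, 30206 and 30130 genes had a value above 0. With 1 library per label, no difference has a replicate check and no p-value is given. Intervals are 95% intervals that cover counting error only. Below, "labelled AAVS1" and "labelled ALB" stand for the libraries labelled AAVS1-PD-L1/CTLA4Ig and ALB-PD-L1/CTLA4Ig.

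The inserted genes were read first, because they check the labels. CD274 stood at 26.8 FPKM (25.8 to 27.9, from 2751 fragments) in the library labelled WT, at 26.1 (25.1 to 27.1, from 2645) in that labelled AAVS1 and at 26.8 (25.8 to 27.9, from 2650) in that labelled ALB. CTLA4 had 17.8 FPKM (16.7 to 19), 14.0 (13 to 15.1) and 17.2 (16.1 to 18.4) in the same order. IGHG1, an immunoglobulin G constant region gene to which the Ig part of CTLA4Ig may be assigned, had 46.3 FPKM (44.7 to 48.0), 41.4 (39.9 to 43.0) and 45.9 (44.2 to 47.5). Neither edited library exceeded the library labelled WT in any of these 3 genes beyond counting error. The ratio of ALB to WT was 1.0 (0.948 to 1.06) for CD274, 0.964 (0.879 to 1.06) for CTLA4 and 0.990 (0.941 to 1.04) for IGHG1. Set against WT, the library labelled AAVS1 had 0.971 (0.920 to 1.02) of the CD274 value, 0.787 (0.714 to 0.867) of CTLA4 and 0.894 (0.850 to 0.941) of IGHG1. No gain from an insert set the edited libraries apart from the library labelled WT, which leaves all 3 labels in doubt. Each library is therefore named by its label throughout, and every direction below is a direction between labels.

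The host genes of both insertion sites also differed little. ALB had 52.5 FPKM in the library labelled WT, 50.4 in that labelled AAVS1 and 53.6 in that labelled ALB, and the ratio of ALB to WT was 1.02 (0.980 to 1.07). PPP1R12C had 9.78, 10.4 and 9.96 FPKM, with a ratio of AAVS1 to WT of 1.06 (0.995 to 1.13). Between the edited libraries, labelled ALB over labelled AAVS1, CTLA4 had a ratio of 1.23 (1.11 to 1.35), IGHG1 1.11 (1.05 to 1.17), ALB 1.06 (1.02 to 1.11), CD274 1.03 (0.976 to 1.09) and PPP1R12C 0.961 (0.901 to 1.02). On GRCh38, CD274 (ENSG00000120217) lies on the forward strand of chromosome 9 from 5450503 to 5470566 and CTLA4 (ENSG00000163599) on that of chromosome 2 from 203867771 to 203873965. IGHG1 (ENSG00000211896) lies on the reverse strand of chromosome 14 from 105736343 to 105743071, ALB (ENSG00000163631) on the forward strand of chromosome 4 from 73397114 to 73421412, and PPP1R12C (ENSG00000125503) on the reverse strand of chromosome 19 from 55090913 to 55117559. The insertion points and the coding sequences inserted are not given in the sources used here. A gene-level value does not separate an inserted copy from the cells' own copy. IGHG2, IGHG3 and IGHG4 were not analysed here.

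**Figure D1:**
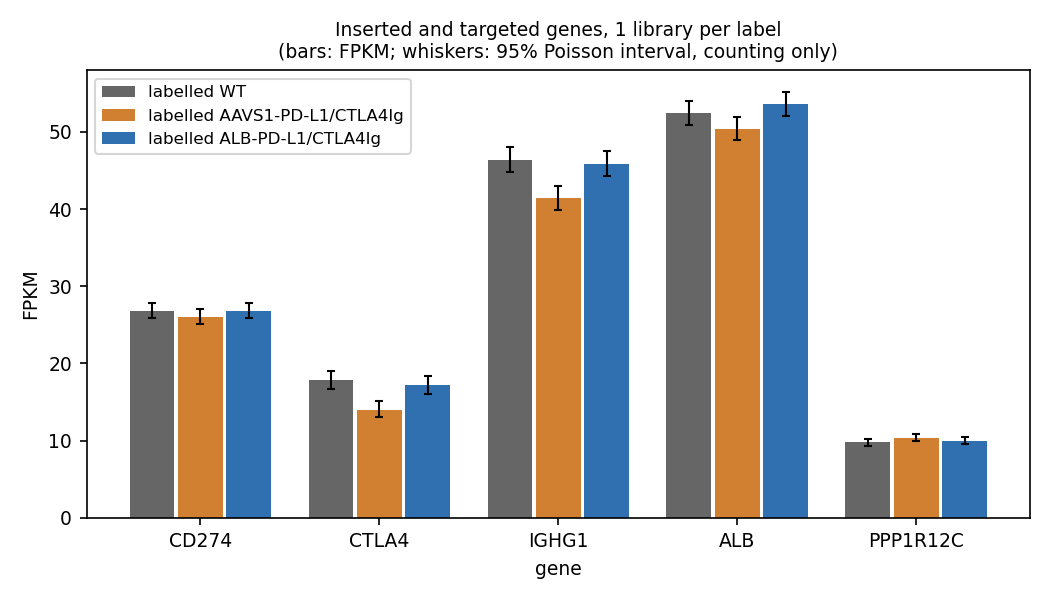
FPKM (vertical axis, from 0) of CD274, CTLA4, IGHG1, ALB and PPP1R12C in the 3 libraries named by their labels; bars are the deposited values of 1 library each and whiskers are 95% Poisson intervals for counting error only. CD274 sits between 26.1 and 26.8 in all 3 libraries, and the library labelled WT shows no lower bar for CTLA4 (17.8) or IGHG1 (46.3).

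Genes of fetal liver, of secreted plasma proteins and of collagen-producing cells were abundant in all 3 libraries. Levels given here and for the lists that follow are means over the 3 libraries, in FPKM. H19 (1238) and AFP (1132), which mark fetal liver, led the list of fetal liver and hepatoblast genes, of which 13 of 14 reached 1 FPKM. Among secreted plasma proteins, 21 of 26 reached 1 FPKM, led by the fibrinogen chain FGB (902) and the thyroxine carrier TTR (761). Among the stellate cell and fibroblast genes the fibrillar collagens COL3A1 (1079) and COL1A1 (421) were highest, and 17 of 18 reached 1 FPKM. CD24 (260.1) and KRT19 (219) led the cholangiocyte list, where all 13 did. The transcription factors CEBPB (18.2) and FOXA3 (13.4) led the hepatocyte factors, of which 14 of 19 reached 1 FPKM.

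Of 18 cytochrome P450 genes of drug metabolism, 4 reached 1 FPKM: CYP1A1 (9.14), CYP3A5 (3.80), CYP1B1 (3.43) and CYP2D6 (2.18). CYP3A4, the main drug-metabolising enzyme of adult liver, had 0.285. Bile acid genes at or above 1 FPKM were CYP27A1 (14.2), HSD17B4 (11.3), SCP2 (5.64), ACOX2 (1.71) and NR0B2 (1.24). The urea cycle and ammonia genes GLUL (67.4), ASS1 (31.9), SLC25A13 (10.4), CPS1 (7.5), ASL (6.55) and SLC25A15 (4.17) were present, as were the amino acid catabolism genes HGD (16.5), PRODH (15.8), CDO1 (11.8), GLDC (5.37), FAH (2.18) and TDO2 (1.06). Among hepatic transporters ABCG2 (8.33) and ABCC3 (4.06) were highest, with 7 of 17 at or above 1 FPKM. Pluripotency genes were led by SOX2 (12.6), DNMT3B (6.84), LIN28A (4.72), ZFP42 (3.3), TDGF1 (3.24) and TERF1 (1.97), while the core factor POU5F1 had 0.108. CYP3A4 and POU5F1 fell outside the rule for named genes and were chosen after their values were seen.

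Some markers of other tissues reached 1 FPKM, at varied levels. In the intestinal list, with a median of 0.347, 4 of 12 did: CDH17 (104), VIL1 (14.5, with 44.0% of its exon length shared with another gene), CDX2 (9.56) and TFF3 (1.71). In the pancreatic and gastric list, with a median of 0.409, 3 of 11 did: PRSS1 (8.98), TFF1 (5.14) and SST (3.14). Of 12 endothelial genes, 2 reached 1 FPKM, KDR (8.62) and TEK (4.93), and the list median was 0.147. Of 11 blood and macrophage genes, 3 did, CSF1R (3.96), LYZ (2.45) and CD163 (1.06), and the list median was 0.0696. Of the immune checkpoint and costimulation list other than CD274, NECTIN2 (122), PVR (116) and CD276 (87.0) stood above CD47 (5.45), TNFSF10 (5.38) and CD200 (4.03). The replication-dependent histone genes, whose main transcripts lack a poly-A tail, held H2BC12 (89.5), H1-2 (42.3), H2BC5 (27.6), H2AC6 (15.2), H2BC21 (4.27) and H4C8 (3.24) at or above 1 FPKM.

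The comparison labelled ALB against labelled WT asks whether insertion at the albumin gene went with other changes of expression. FTH1, the heavy chain of the iron store ferritin, was the 1 protein-coding gene past 2-fold on the log2(FPKM + 1) scale, at 15.5 FPKM in the library labelled ALB against 48.9 in that labelled WT (ratio 0.317, 0.292 to 0.344). ARPC5, a subunit of the actin-nucleating Arp2/3 complex, was higher at 10.2 against 6.17 FPKM (ratio 1.65, 1.55 to 1.75). Next by log2 difference, with their ratios, came KLRF2 (1.31), MRPL15 of the mitochondrial ribosome (1.29), TRIAP1, an inhibitor of apoptosis (1.29), ZNF165 (1.28), the linker histone H1-2 (1.22), COPS9 of the COP9 signalosome (1.24) and ISM2 (1.24). After FTH1, the lowest by log2 difference were ZNF428 (0.602), TMEM160 (0.610), TRIR (0.664), METTL26 (0.671), the prohormone convertase inhibitor PCSK1N (0.690), the neuropeptide NMB (0.706) and the extracellular superoxide dismutase SOD3 (0.721). These directions are between labels, and the target genes leave both labels in doubt. Of the exon length of FTH1, 62.4% lies in exons of another gene too, mostly BEST1, and of ZNF428 27.6%, mostly SRRM5; the sources used here do not say whether the counting used strand, so these values are uncertain.

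Of 41 gene lists with a percentile, 40 had medians within 0.1 of 0 on the log2 scale for ALB against WT, and 4 stood apart from random lists of like expression, where 2.05 would do so by definition. The 13 protein-coding genes of the mitochondrial genome, for subunits of the respiratory chain and of ATP synthase, had a median of −0.08 (percentile 0.01), and 11 of 13 were lower. MT-CO1 had 4370.4 against 4492 FPKM and MT-CO2 3401 against 3603, while MT-CO3 was highest by ratio (0.03) and MT-ATP8 lowest (−0.47, from 1.41 and 2.32 FPKM, with 22.2% of its exon length shared and a ratio interval of 0.202 to 1.67). The cardiac and skeletal muscle list had a median of −0.17 (percentile 0.53), with DES at −0.43, MYL7 at −0.20, NKX2-5 at −0.17, TNNT2 at −0.03 and ACTC1 at 0.00, all under 6 FPKM. Acute phase genes, which the liver secretes in inflammation, had a median of 0.07 (percentile 99.2), although the most abundant, HP, was the lowest at −0.09 (92.6 against 98.6 FPKM); SAA1 stood at 0.11 and FGL1 highest at 0.15. That median turned to −0.01 (percentile 26.1) with genes at a mean of at least 5 FPKM, and as a mean of members the list stood at percentile 82.6. Heat shock and immediate early genes had a median of −0.03 (percentile 1.42), with HSPB1 lowest at −0.34 (112 against 142 FPKM), DNAJB1 at 0.01 and FOSB highest at 0.16. As means of members, neither the muscle list (percentile 2.75) nor the heat shock list (9.79) stood apart.

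No other list with a percentile stood apart for ALB against WT. The liver lists had medians of 0.03 for secreted plasma proteins, −0.01 for coagulation, −0.04 for complement, 0.01 for cytochromes P450, 0.01 for phase II conjugation, −0.03 for transporters, 0.01 for bile acid synthesis, 0.04 for the urea cycle, −0.04 for amino acid catabolism, 0.01 for gluconeogenesis, 0.01 for lipoproteins, 0.00 for cholesterol synthesis, 0.00 for hepatocyte factors and −0.03 for fetal liver. Lists of other cell types had medians of 0.02 for pluripotency, −0.03 for definitive endoderm, −0.02 for cholangiocytes, −0.01 for intestine, 0.04 for stellate cells and fibroblasts and 0.03 for neural genes. Immune lists had medians of 0.02 for HLA class I, 0.01 for HLA class II, −0.05 for checkpoint genes, −0.03 for the interferon response and −0.03 for NF-kB targets. The remaining medians were −0.01 for the cell cycle, −0.01 for replication-dependent histones, 0.01 for nuclear oxidative phosphorylation genes, 0.01 for ribosomal proteins, −0.01 for the neighbours of ALB, −0.01 for those of PPP1R12C and −0.02 for TGF-beta and Wnt targets. The 4 genes of the edited loci had a median of 0.01. Lists with fewer than 4 members got values alone. KDR and TEK were higher, PRSS1, TFF1 and SST were lower, and CSF1R and LYZ were lower with CD163 higher, none beyond counting error.

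Across genes of all types, 26 were at least 2-fold higher and 25 at least 2-fold lower in the library labelled ALB than in that labelled WT, of 13501 with a mean of at least 1 FPKM. Of these, 26 and 24 rested on fewer than 50 fragments in both libraries together, and 23 and 22 were small RNA genes. Libraries simulated to differ by counting error alone gave means of 19.9 (range 6 to 31) and 20.6 (13 to 32). Among 6762 protein-coding genes with a mean of at least 5 FPKM, 5 were at least 1.25-fold higher with an interval clear of 1, and 26 lower.

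**Figure D2:**
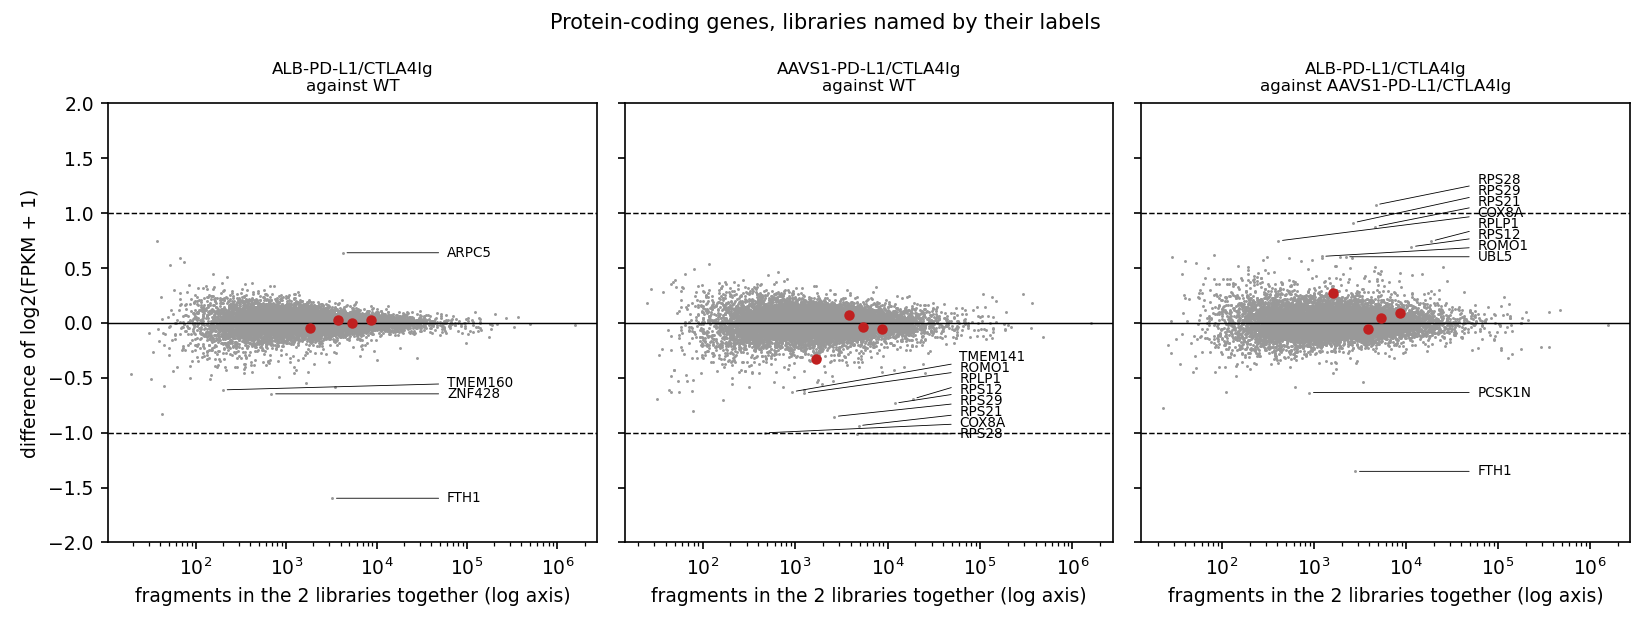
Difference of log2(FPKM + 1) (vertical axis) against the fragments of both libraries together (log axis) for protein-coding genes with a mean of at least 1 FPKM, with 1 panel per comparison of libraries named by their labels. Red points are CD274, CTLA4, ALB and PPP1R12C, dashed lines mark 2-fold and named points are genes of the naming rule at or beyond 0.6; FTH1 lies at −1.60 for ALB against WT and RPS28 at −1.01 for AAVS1 against WT.

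The comparison labelled AAVS1 against labelled WT asks the same of insertion at AAVS1. Several ribosomal protein genes were lower in the library labelled AAVS1: RPS28 at 29 against 59.4 FPKM (ratio 0.488, 0.459 to 0.519), RPS21 at 65.3 against 126 (0.519), RPS29 at 3.58 against 7.27 (0.492), RPS12 at 235 against 392 (0.601) and RPLP1 at 88.3 against 143 (0.616). COX8A, a subunit of cytochrome c oxidase, was lower at 12.2 against 25.5 FPKM (ratio 0.480, 0.393 to 0.583), as were ROMO1 of the inner mitochondrial membrane (0.634) and TMEM141 (0.625). Highest by log2 difference, with their ratios, were the chaperone subunit PFDN4 (1.43, 1.20 to 1.71), NHP2 of small nucleolar ribonucleoproteins (1.36), MRPL15 (1.33), the chromatin reader ING2 (1.33), HPF1, a cofactor of poly-ADP-ribosylation (1.31), TAF9 of the TFIID complex (1.28), the protease inhibitor TFPI2 (1.28) and the mitochondrial gene MT-ND3 (1.25). On the log2(FPKM + 1) scale RPS28 and COX8A were the protein-coding genes past 2-fold; RPS29, past it by the ratio of FPKM, stood at −0.85 there. Each direction is again between labels, with both labels in doubt. Exon length shared with other genes was 21.4% for RPS28, 34.5% for COX8A, 16.5% for TMEM141, 12.5% for ROMO1, 27.4% for NHP2 and 27.2% for TAF9, and ribosomal protein genes have many near-identical pseudogenes, so their values are uncertain.

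Of the 41 lists, 38 medians for AAVS1 against WT lay within 0.1 of 0 and 4 lists stood apart. Ribosomal protein genes had a median of −0.11 (percentile 0.01) and 16 of 20 were lower. RPL8 had 339 against 361 FPKM (−0.09) and RPS2 354 against 359 (−0.02), with RPS12 lowest (−0.73) and RPS6 highest (0.17) among list members. RPS28, RPS21 and RPS29, named above, are not in the list. Mitochondrially encoded genes had a median of 0.15, above all 10000 random lists, and 11 of 13 were higher. MT-CO1 had 5083 against 4492 FPKM (0.18) and MT-CO2 4250.4 against 3603 (0.24), with MT-ND3 highest (0.32) and MT-ND6 lowest (−0.20). Nuclear genes of oxidative phosphorylation had a median of −0.09 (percentile 0.13) and 17 of 18 were lower, with SDHB the exception (0.07). Among the lower were ATP5F1B (−0.06), UQCRC1 (−0.10) and, lowest in the list, NDUFA1 (−0.31, with 44.5% of its exon length shared). The list does not hold COX8A. Neural genes had a median of 0.12 (percentile 98.6), with STMN2 at 0.15 (37.0 against 33.2 FPKM), NES at 0.12, TUBB3 at 0.11 (35.8% shared) and MAP2 at 0.07; as a mean of members the list no longer stood apart (percentile 95.9). The mitochondrial chromosome held 3.50% of fragments in the library labelled AAVS1, 3.14% in that labelled WT and 3.03% in that labelled ALB.

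No other list with a percentile stood apart for AAVS1 against WT. Among liver lists the medians were 0.02 for secreted plasma proteins, 0.01 for acute phase genes, −0.03 for coagulation, −0.03 for complement, −0.10 for cytochromes P450, −0.03 for phase II conjugation, −0.04 for transporters, −0.06 for bile acid synthesis, 0.02 for the urea cycle, −0.07 for amino acid catabolism, −0.05 for gluconeogenesis, −0.02 for lipoproteins, −0.04 for cholesterol synthesis, 0.02 for hepatocyte factors and −0.01 for fetal liver. For other cell types they were 0.01 for pluripotency, 0.03 for definitive endoderm, 0.01 for cholangiocytes, −0.01 for intestine, 0.05 for stellate cells and fibroblasts and −0.07 for muscle. For immune lists they were 0.01 for HLA class I, −0.06 for HLA class II, 0.02 for checkpoint genes, 0.01 for the interferon response and 0.02 for NF-kB targets. The others were −0.02 for the cell cycle, 0.03 for heat shock and immediate early genes, −0.02 for histones, 0.01 for the neighbours of ALB, −0.08 for those of PPP1R12C, −0.01 for TGF-beta and Wnt targets and −0.05 for the edited loci. At least 2-fold, 28 genes were higher and 29 lower, of which 28 and 25 had fewer than 50 fragments. Simulated counting error alone gave means of 19.4 (range 10 to 31) and 20.4 (12 to 32). At 1.25-fold with an interval clear of 1, 15 protein-coding genes were higher and 68 lower.

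The comparison of the edited libraries, labelled ALB against labelled AAVS1, does not involve the WT label, but the target genes leave these labels unchecked too. With 1 library each, the insertion site cannot be told apart from differences between cultures or library preparations. RPS28 (62.2 against 29 FPKM, ratio 2.14, 2.02 to 2.28), RPS29 (2.13), RPS21 (1.85), RPLP1 (1.68) and RPS12 (1.62) were higher in the library labelled ALB, together with COX8A (1.73), UBL5, a ubiquitin-like protein (1.55), and ROMO1 (1.54). FTH1 was lower at 15.5 against 41.1 FPKM (ratio 0.377, 0.346 to 0.410), followed by PCSK1N (0.623), TRIR (0.685), the nucleolar protein NOL7 (0.717), SOD3 (0.734), PAIP2, an inhibitor of translation (0.757), OCEL1 (0.759) and CEBPD, a transcription factor of the acute phase response (0.767). On the log2(FPKM + 1) scale RPS28 and FTH1 were the protein-coding genes past 2-fold; RPS29, past it by the ratio of FPKM, stood at 0.91 there. The limits given above for FTH1, RPS28, COX8A, ROMO1 and ribosomal protein genes hold here too, and PAIP2 shares 21.0% and NOL7 18.6% of exon length with another gene.

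Between the edited libraries 8 of 41 lists stood apart and 36 medians lay within 0.1 of 0. Mitochondrially encoded genes were lower in the library labelled ALB (median −0.24, below all 10000 random lists, 12 of 13 lower), with MT-CO1 at −0.22, MT-CO2 at −0.32, MT-ATP8 lowest (−0.78) and MT-ND4L highest (0.08). The low level and shared exon length of MT-ATP8, given above for ALB against WT, limit its value here too. Ribosomal protein genes were higher (median 0.12, percentile 99.97, 14 of 20 higher), with RPL8 at 0.15 and RPS2 at −0.08. Among list members, which leave out RPS28, RPS29 and RPS21, RPLP1 was highest (0.74) and RPL13 lowest (−0.21). Nuclear oxidative phosphorylation genes were higher too (median 0.08, percentile 99.6, 16 of 18 higher), with ATP5F1B at 0.08 and UQCRC1 at 0.06. Among list members, which leave out COX8A, COX5B was highest (0.38) and SDHB lowest (−0.13). HLA class II genes, which present antigen to helper T cells, had a median of 0.13 (percentile 99.2), and the 6 of 10 members that reached 1 FPKM were all higher: HLA-DPB1 (0.22), HLA-DMA (0.21), HLA-DQB1 (0.19), HLA-DRB1 (0.07), CD74 (0.03) and HLA-DPA1 (0.02). Intervals for HLA-DPB1 and HLA-DQB1 were clear of 1. HLA-DRB1 had a mean of 98.5 FPKM, but its partner HLA-DRA 0.11, with HLA-DQA1 at 0.39, HLA-DMB at 0.39 and the class II activator CIITA at 0.094. Definitive endoderm genes had a median of −0.12 (percentile 0.46), with SOX17 at −0.28, GATA6 at −0.20, KIT at −0.14, GATA4 at −0.09, FOXA2 at −0.07 and CXCR4 at 0.04. Heat shock and immediate early genes had a median of −0.07 (percentile 0.925), with HSPB1 lowest (−0.27), DNAJB1 at −0.04 and IER2 highest (0.38, with 30.8% of its exon length shared). NF-kB targets had a median of −0.06 (percentile 2.22), with CXCL5 at 0.06, ICAM1 at −0.02, CXCL8 highest (0.20) and CXCL2 lowest (−0.34). The neighbours of PPP1R12C had a median of 0.11 (percentile 97.8), with HSPBP1 highest (0.37), TNNT1 at 0.14 and EPS8L1 lowest (−0.02). In this comparison the mitochondrial, ribosomal and oxidative phosphorylation lists stayed apart in all 6 alternative settings and the NF-kB list in 3 of 6. As a mean of members, HLA class II (percentile 94.7), heat shock and immediate early genes (3.72) and the neighbours of PPP1R12C (94.3) no longer stood apart, nor did definitive endoderm at a mean of at least 5 FPKM (−0.08, percentile 4.11).

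At least 2-fold, 24 genes were higher and 28 lower in the library labelled ALB than in that labelled AAVS1, of which 21 and 26 had fewer than 50 fragments. Simulated counting error alone gave means of 21.1 (range 9 to 31) and 20.02 (12 to 31). At 1.25-fold with an interval clear of 1, 82 protein-coding genes were higher and 26 lower. For protein-coding genes with at least 2000 fragments in both libraries together, the spread of ratios beyond counting error was 2.69% for ALB against WT, 5.67% for AAVS1 against WT and 5.81% for ALB against AAVS1. Of these genes, 96.9%, 87.3% and 86.4% lay within 1.1-fold. Among 115 genes with a range of at least 2-fold over the 3 libraries, the library farther from the middle value was that labelled WT in 19 genes above and 20 below, AAVS1 in 18 and 21, and ALB in 16 and 21. Most genes past 2-fold in each comparison had fewer than 50 fragments, and no simulated tally was made. An even tally therefore does not show that no library stands apart among genes with many fragments. The ratios of both edited libraries to WT correlated across 11632 protein-coding genes with Pearson's r of 0.359 (covariance 0.00337). Unchanged libraries simulated against the same WT library gave 0.494 (0.00259), and genes are not independent replicates.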

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

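The counts with protein-coding genes alone and with at least 50 fragments were chosen after the results were seen; the other alternatives were fixed beforehand. The counts of genes past 2-fold depended on how low values were treated, less on scaling by size factors or without the 50 most abundant genes. Higher and lower genes numbered 61 and 66 for ALB against WT, 62 and 75 for AAVS1 against WT, and 75 and 88 for ALB against AAVS1 at a pseudocount of 0.1. Rescaled to the common sum of TPM, where the pseudocount weighs less by construction, they numbered 57 and 55, 53 and 64, and 69 and 77. With no filter they numbered 53 and 56, 65 and 61, and 60 and 65. At a mean of at least 5 FPKM they numbered 0 and 1, 0 and 6, and 5 and 3, with fewer genes compared by construction. With protein-coding genes alone they numbered 0 and 1, 0 and 2, and 1 and 1, and with at least 50 fragments 0 and 1, 0 and 4, and 3 and 2. Within 1.5 times of the reported counts were those with median-ratio size factors (25 and 25, 28 and 29, 24 and 29), without the 50 most abundant genes (25 and 25, 28 and 25, 22 and 31) and with rows of 1 symbol summed (20 and 24, 24 and 26, 22 and 26).

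Of 93 alternatives for the lists that stood apart, 81 left the list apart and 12 did not. As a mean of members the call was lost for acute phase (percentile 82.6), muscle (2.75) and heat shock genes (9.79) in ALB against WT, neural genes in AAVS1 against WT (95.9), and HLA class II (94.7), NF-kB (3.77), heat shock genes (3.72) and the neighbours of PPP1R12C (94.3) in ALB against AAVS1. At a mean of at least 5 FPKM it was lost for acute phase genes (26.1) and definitive endoderm (4.11), and for NF-kB also at a pseudocount of 0.1 (3.01) and at the common sum of TPM (2.94). The value itself stayed in place in 87 of the 93. The acute phase median for ALB against WT reversed to −0.0139 at a mean of at least 5 FPKM, where fewer members remained by construction, and was 0.0408 as a mean of members. Means of members in place of medians gave −0.11 for mitochondrial genes in ALB against WT, −0.17 for ribosomal genes in AAVS1 against WT, and 0.16 for ribosomal and 0.12 for oxidative phosphorylation genes in ALB against AAVS1, and the cause was not tested. Of 252 alternatives for named gene ratios, 248 left the value in place, 4 moved it, all for RPS29, and 0 reversed it. Scalings moved the median of all genes by little, to 0.02 at most. Depth limits genes under 50 fragments most, and the lack of replicates limits every difference.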

Other observations

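Except for the tests of length and GC content, of pseudogenes of ribosomal protein genes and of uncounted ribosomal fragments, all tests of explanations below were chosen only after the result was seen. GDF15 (mean 651 FPKM), a secreted stress cytokine, and the cell cycle inhibitor CDKN1A (205) led the p53 targets, whose median difference was 0.04 for ALB against WT, 0.01 for AAVS1 against WT and 0.02 for ALB against AAVS1. The chaperones HSPA5 (717) and HSP90B1 (241) led the unfolded protein response, with medians of 0.00, 0.00 and 0.02. Its member SDF2L1, a chaperone cofactor of the endoplasmic reticulum, had 32.6 FPKM in the library labelled ALB and 32.1 in that labelled AAVS1 against 42.6 in that labelled WT (−0.38 and −0.40 on the log2 scale). ENO1 (270.3) and ENO2 (117) led hypoxia and glycolysis (0.02, −0.03 and 0.03), and the haem oxygenase HMOX1 (205) and MT2A (53.7) led the metal response (0.06, 0.03 and −0.01), of which 7 of 11 genes reached 1 FPKM. None of these lists stood apart from random lists.

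Several genes that overlap a neighbour had low values for their class, and they were picked after their values were seen. FTH1 had a mean of 35.2 FPKM and FTL, the light chain of the same ferritin shell, 6622, the highest of all protein-coding genes. IGF2 shares 75.0% of its exon length with another gene and had 3.33 FPKM, while H19, its imprinted neighbour, had 1238. The glycolytic enzyme ALDOA shares 53.5% and had 0.96 FPKM. None of CD274, CTLA4, IGHG1 or ALB shares exon length with another gene.

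CD274, CTLA4 and IGHG1 stood at like levels in all 3 libraries, so they set no label apart. Silent endogenous copies with inserted genes absent from WT were excluded by CTLA4, at 1.14 (1.05 to 1.24) in WT over both edited libraries. With endogenous copies silent, labels swapped among the 3 would leave a library nearly without IGHG1. The lowest library had 0.894 (0.850 to 0.941) of the highest, which excludes a swap in that case only. If the cells express their own copies, like levels say nothing about label order, and a swap stays open. RNA of lymphocytes or plasma cells was excluded by 46 fragments of PTPRC, CD3E, CD79A, IGKC and JCHAIN against 4146 of CTLA4 and IGHG1 in the library labelled WT, a ratio of 0.0111 (0.00811 to 0.0148). A library labelled WT that was made from cells carrying the insert may be the source: the spread beyond counting of ALB against WT was 0.470 of that of ALB against AAVS1. That test could have come out the other way but shows only that the libraries labelled WT and ALB are close. CTLA4 gave 22.96% of the fragments of CTLA4 and IGHG1 in the library labelled WT (21.7 to 24.3), 20.8% in AAVS1 (19.5 to 22.1) and 22.5% in ALB (21.2 to 23.8). Genes at like levels give near-equal shares whatever their source, so these shares do not tell 1 fused transcript from separate ones. Expression of both genes by the cells themselves stays open because inserted and endogenous copies were not separated, and no biological explanation was tested.

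Ribosomal protein genes were lower and mitochondrial genes higher in the library labelled AAVS1 than in that labelled WT. A smooth trend with transcript length and GC content was excluded as the whole cause, because with it removed the medians were still −0.0960 (random lists −0.0473 to 0.0452) and 0.130 (−0.0613 to 0.0581). Length was the median over a gene's annotated coding transcripts, and the smoothing was broad. A steep change confined to the shortest transcripts could therefore have been missed. Fragments assigned to processed pseudogenes instead were excluded for the ribosomal genes, since 155 pseudogenes lost fragments as well, with a gain over loss of −0.0348 (−0.0462 to −0.0233). Ribosomal fragments left partly uncounted in that library might explain the ribosomal part: the 10 members with the higher FPKM had a median of −0.0783, just inside random lists (percentile 3.02, from −0.0816), and the 10 lower ones −0.166. The margin is narrow, and 8 of 10 members were lower in each group. The groups follow FPKM, which divides by joined exon length, and not the number of fragments. RPLP1, with 11696 fragments in the library labelled WT, was in the lower group and RPS12, with 7495, in the higher. The split therefore does not decide this explanation. A difference between the edited cells, between cultures or between library preparations stays open and untested.

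FTH1 was low in the library labelled ALB alone. Fragments assigned to its 14 pseudogenes instead were excluded by a gain over loss of −0.0322 (−0.0681 to 0.00372), and less complete counting of genes with many pseudogenes by the other 46 genes with at least 10 pseudogenes, whose median was 0.0155 and lowest value −0.166. Loss, in that library alone, of the part shared with another gene was tested next. The 55 other genes with at least 50% of their exon length shared had a median of −0.0271. Their lowest value was −0.584 against −1.66 for FTH1, so none of them fell as far. They were picked by exon length, and the fragments in their shared part were not measured. Such a loss is therefore not excluded for FTH1. The same loss in all 3 libraries, which could leave a less steady remainder, stays open: 2 of those 55 (3.64%), IGF2 and PRELID1, both lower, lay past 1.25-fold, against 27 of 7245 (0.373%) of genes under 5% shared, a ratio of 9.76 (1.12 to 38.8) that rests on 2 genes, neither of which fell as far as FTH1. A change of FTH1 that goes with insertion at ALB stays open, as untested.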
